A study of Homo sapiens with 4 samples.

How the data were processed

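Human cord blood CD34+ cells and the leukaemic line U937 were treated with EET or DMSO, and 1 RNA sequencing library was made per cell type and treatment, per the labels. RNA was depleted of ribosomal RNA before library preparation and sequenced as paired ends on an Illumina instrument, per the labels' protocols. U937 cells were briefly kept without serum before treatment and the CD34+ cells were treated in serum-free medium, per the labels' protocols. The submitters' processing notes name cutadapt, TopHat2 2.0.11, Cufflinks 2.2.1 and the genome build hg19, without roles or order. Nothing in the sources used here says that strand was kept, so reads from overlapping genes on opposite strands cannot be told apart.

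The deposited data are 2 tables, each comparing 2 conditions gene by gene, per the file headers. In the U937 table the authors gave FPKM per gene for each condition, a test status, a test statistic and p-values and q-values. The U937 column taken as EET carries a condition name that ends in 10, which the labels do not explain, while the labels give a dose of 5 µM. In the CD34+ table the authors gave log2 ratios, a test statistic, p-values and q-values for conditions named only as the first and second, per the file headers. The 2 per-sample FPKM columns of the CD34+ table were therefore not used, and only its comparison columns were. The authors' log2 ratio in that table is the second condition over the first, and its p-value is the two-sided normal tail of its test statistic, within 2.73e-06 for every tested gene. The p-values of the U937 table are multiples of 5e-05, so the p-values of both tables were not computed alike, and the sources used here do not say how. The authors' significance mark corresponds to a q-value under 0.05.

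The U937 table holds 23615 rows, of which 10413 are marked as tested. The CD34+ table holds 23569 rows, of which 14880 are marked as tested and 170 of those have an infinite ratio, which was left out. Of the U937 test statistics, 78 are unreadable spreadsheet errors, and 28 symbols of each table had been turned into dates by a spreadsheet. Those rows were counted but not named. Positions are the loci of the table in hg19, written 1-based, and a locus can span several overlapping genes. Depth was examined through the low genes. Of 3578 weakly measured CD34+ genes, 55.0% had a log2 ratio within 0.001 of a ratio of whole numbers up to 8, shifted by -0.12 (against 0.75% at a typical other shift), so a read was worth 1.09 times as much in the first-listed as in the second-listed condition. The same search in 1902 low U937 genes found 3.00%, against 1.79% at a typical other shift, and gave no depth.

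For U937, log2((EET + 1)/(DMSO + 1)) was computed from the deposited FPKM for genes with a mean of at least 1 FPKM, and a 2-fold difference (1 on the log2 scale) was the size threshold. With 1 library per group no test and no p-value of this work is given. For CD34+ cells the authors' deposited log2 ratios of tested genes were used under the same threshold. The standard error quoted for single genes is the one implied by the authors' test statistic, that is, the log2 ratio without a pseudocount divided by that statistic. It reflects the spread that the authors' program assumed and holds no replicates.

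Before the data were examined, 32 gene lists were fixed for pathways, stress responses, housekeeping functions and blood cell types. For each list with at least 5 measured members, the median log2 ratio was set against 10000 random lists of the same size. Random lists were matched on mean expression in 20 bins for U937. For CD34+ cells they were matched in 20 bins of the implied standard error, which replaces the planned matching on expression. A list stood apart at a percentile of at most 2.5 or at least 97.5, which describes these libraries and is not a p-value. For U937, 27 lists had enough members.

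Genes were named by a rule fixed before the data were examined. It covers FOS, FOSB, FOSL1, FOSL2, JUN, JUNB, JUND, ATF3, RUNX1, CD34, CXCR4 and EPHX2, the 12 highest and 12 lowest tested genes per cell type, up to 10 genes shared at 2-fold in each direction, and up to 4 members per list with the largest log2 ratios. For CD34+ cells the FPKM filter of this rule could not be applied, so the genes marked significant in the authors' deposited table took the place of the highest and lowest genes. That choice, and the naming of the 11 U937 genes with a q-value under 0.1 in the authors' deposited table and of BLOC1S5-TXNDC5, HIST1H1T and HIST1H4L as shared genes, were made after the values were seen. Genes shared between cell types are given without a treatment direction, and the planned difference of both responses per gene was not computed for the same reason.

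GC content and transcript length were taken by symbol from the GENCODE release 29 transcripts, as the median over a gene's transcripts. A value was found for 97.7% of U937 genes and 95.9% of CD34+ genes, and for 80 of the 86 longer genes lower in U937. Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, centring on the median, leaving out small RNA genes, tested genes only and a threshold of 1.5-fold. Subtracting the median log2 ratio of 20 GC bins, leaving out genes that share a locus or are listed at 0, and q-value thresholds of 0.01 and 0.1 were added after the data were examined.

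The procedures were tested on simulated data. With U937 ratios shuffled among genes of like expression, 2 of the 27 real lists and 2.5% of random lists stood apart, and a shift of 0.3 was found for 96.3% of the 27 lists. With CD34+ ratios shuffled likewise, 0 of the 32 real lists and 4% of random lists stood apart, and a shift of 0.3 was found for all 32 lists. In simulated U937 values over 10627 genes with a spread of 0.24, the size threshold was met by 44% of genes changed 2-fold, 90% of those changed 3-fold and 100% of those changed 4-fold, and by 0% of unchanged genes. That simulation gave every gene the same spread, so it cannot tell how often noisier genes pass the threshold unchanged. The implied standard error was 2.13 for CHAC1 and 3.94 for RCAN3AS, which both passed it. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.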

Results

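Gene expression was measured in 2 kinds of human blood cells that had been given the lipid 11,12-epoxyeicosatrienoic acid (EET) or only its solvent, dimethyl sulfoxide (DMSO). EETs are signalling lipids that cytochrome P450 enzymes make from arachidonic acid. One cell type was CD34+ cells from cord blood, a population rich in haematopoietic stem and progenitor cells. The other was U937, an established leukaemic line with features of monocytes. Per the labels, each treatment lasted 2 h at an EET dose of 5 µM, and total RNA depleted of ribosomal RNA was sequenced. The U937 condition taken as EET carries a name that ends in 10, which the labels do not explain. There were 4 libraries, 1 per cell type and treatment, so no difference below has a replicate check and no test across samples was possible. The depth of the U937 libraries is unknown, because the values are FPKM (fragments per kilobase of transcript, scaled to library size) without counts. Summed over all genes, FPKM came to 1285330 in the U937 DMSO library and 1514090 in the U937 EET library. The CD34+ table names its conditions only as the first and the second, so its values are given as second-listed over first-listed condition and carry no treatment direction.

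The U937 comparison asks which transcripts differ in abundance after exposure to EET. PLIN2, which codes for a coat protein of lipid droplets, stood at 22.4 FPKM in DMSO and 169 FPKM in EET, 7.55-fold higher. DDIT4, an inhibitor of mTORC1 signalling, stood at 19.3 and 127 FPKM, 6.61-fold higher. The AP-1 subunit gene FOS was 4.91-fold higher, at 1.98 FPKM in DMSO and 9.72 FPKM in EET. At the other end, MIF, the gene of macrophage migration inhibitory factor, stood at 268 FPKM in DMSO and 80.5 FPKM in EET. The chromatin gene MBD3 was lower at 42.8 and 15.1 FPKM, and SIVA1, a gene of apoptosis signalling, at 110 and 36.3 FPKM. On the log2(FPKM + 1) scale used below, which understates the differences of low genes, the EET over DMSO ratio was 2.86 for PLIN2, 2.66 for DDIT4, 1.85 for FOS, -1.72 for MIF, -1.44 for MBD3 and -1.58 for SIVA1. The standard errors implied by the test statistics of the authors' deposited table, which belong to log2 ratios taken without the added 1, were 0.30 for PLIN2, 0.31 for DDIT4, 0.49 for FOS, 0.34 for MIF, 0.31 for MBD3 and 0.35 for SIVA1. These genes lie, in hg19, on chromosome 9 from 19115759 to 19127604 (PLIN2), chromosome 10 from 74033677 to 74035797 (DDIT4) and chromosome 14 from 75745481 to 75748937 (FOS). MIF lies on chromosome 22 from 24235897 to 24241117, in a locus it shares with 1 other gene of the table.

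Among 10627 genes with a mean of at least 1 FPKM, 132 were at least 2-fold higher and 130 at least 2-fold lower with EET. Small RNA genes made up 90 of the higher and 44 of the lower genes, with 74 and 18 snoRNA genes and 6 and 19 microRNA genes among them, leaving 42 and 86 longer genes. Among longer genes with values in both libraries, the highest after PLIN2 and DDIT4 were OSM, the gene of the cytokine oncostatin M (0.43 and 7.08 FPKM in DMSO and EET), and RGS1, a regulator of G protein signalling (0.61 and 5.44 FPKM). LOC100289361 (0.28 and 3.63 FPKM), HIST1H1T (0.38 and 3.36 FPKM) and CHAC1, a glutathione-degrading enzyme (0.11 and 2.39 FPKM), were also among the 12 highest. RNF5 on a chromosome 6 haplotype contig and IDH1-AS1 were listed at 0 with DMSO and at 7.44 and 2.25 FPKM with EET. DDIT3 (13.4 and 44.5 FPKM) and RCAN3AS (0.73 and 4.70 FPKM) share their loci with other genes of the table, so reads may have been split between overlapping genes. Against log2 ratios taken without the added 1, the implied standard error was 1.12 for DDIT3 (ratio 1.73) and 3.94 for RCAN3AS (ratio 2.68).

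The 12 lowest longer genes included the ATP synthase subunit gene ATP5D (36.5 and 9.59 FPKM in DMSO and EET), the histone gene HIST3H2A (56.3 and 8.36 FPKM) and MIF. HIST1H4L, METRN, TMEM238 and C19orf71 stood at 3.62, 3.34, 2.96 and 2.29 FPKM with DMSO and were listed at 0 with EET. HIATL2 (4.44 and 0.41 FPKM), BRICD5 (3.48 and 0.20 FPKM) and FAM173A (5.64 and 0.93 FPKM) were low in both libraries. The read-through gene HOXA10-HOXA9 was lower, at 14.1 and 0.58 FPKM, while HOXA9, in the same locus of 5 genes, was higher at 6.21 and 17.4 FPKM. PHOSPHO2-KLHL23, another read-through gene, stood at 3.81 and 0.0012 FPKM in a locus of 3 genes.

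In the authors' deposited table no U937 gene was marked significant. The smallest q-value in the authors' deposited table was 0.058, shared by 9 genes that each carry the smallest p-value it lists, 5e-05. These were PLIN2, DDIT4, ARRDC3 and the cAMP phosphodiesterase gene PDE4B, all higher with EET, and MIF, MBD3, SIVA1, LINGO3 and LYL1, all lower. ARRDC3 stood at 1.65 and 6.67 FPKM and PDE4B at 1.43 and 5.78 FPKM in DMSO and EET. LYL1, a transcription factor gene of early blood cells, stood at 76.2 and 32.0 FPKM, and LINGO3 at 1.81 FPKM and listed at 0. FOS and ELANE followed with a q-value of 0.095 in the authors' deposited table. By the authors' deposited table, 325 of 10413 tested U937 genes had a p-value under 0.05, fewer than the 521 expected by chance.

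**Figure D1:**
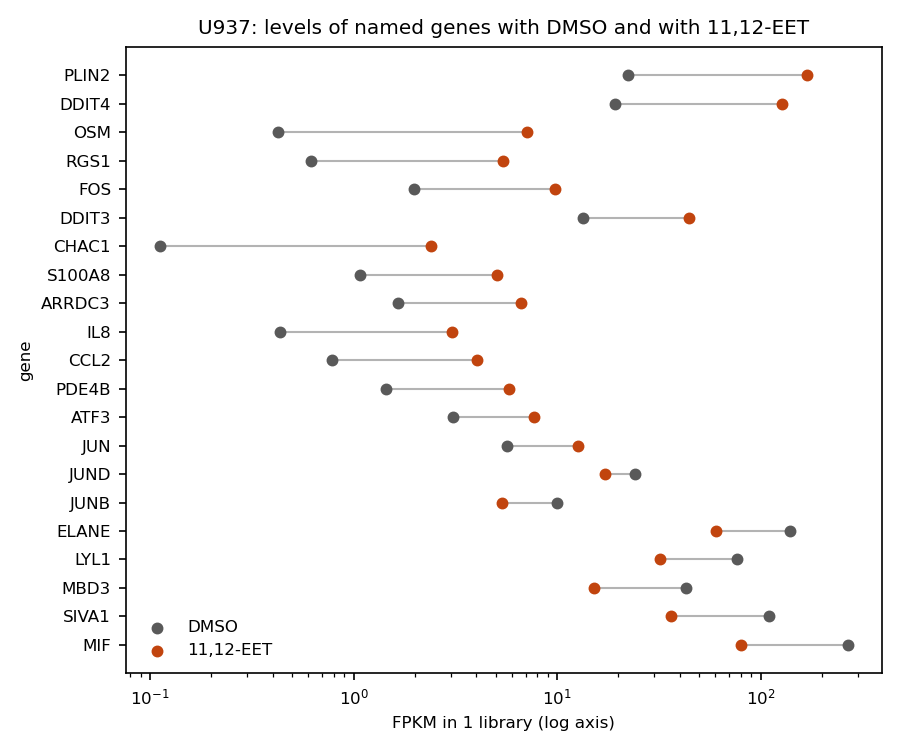
FPKM of named U937 genes in the DMSO library (grey) and the EET library (orange) on a log axis, 1 library each, ordered by the log2 ratio. PLIN2 stands at 22.4 and 169 FPKM at the top and MIF at 268 and 80.5 FPKM near the bottom.

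AP-1 genes are named in published work on EET in blood stem cells, so this list is not independent evidence of a direction. In U937, 3 of the 11 measured AP-1 genes were at least 2-fold higher with EET, none was 2-fold lower, and 8 differed by less. FOS (log2 ratio 1.85), ATF3 (1.09; 3.09 and 7.73 FPKM) and JUN (1.04; 5.66 and 12.7 FPKM) were the 3. JUNB stood at -0.78, JUND at -0.46, FOSB at 0.56 and FOSL2 at 0.29, while FOSL1 was below 1 FPKM in both libraries. The list median of -0.09 lay at percentile 14.35 of 10000 random lists matched on expression, so the family as a whole did not stand apart. With the GC trend described below subtracted, the median turned to 0.15 at percentile 96.2, and JUNB and JUND, which are GC-rich, stood at -0.27 and 0.05. Of 24 other immediate-early genes, 3 were at least 2-fold higher: RGS1 (2.00), KLF10 (1.14) and the phosphatase gene DUSP1 (1.03). PHLDA1 stood at 0.94, and the list median of 0.05 lay at percentile 76.6.

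Of 16 measured NF-kB targets and inflammatory cytokine genes, OSM, the neutrophil chemokine gene IL8 (0.43 and 3.06 FPKM in DMSO and EET) and the monocyte chemokine gene CCL2 (0.78 and 4.02 FPKM) were at least 2-fold higher with EET. The other 13 members differed by less than 2-fold, PLAU standing at 0.73, and the list median of -0.01 lay at percentile 47.4. Most cytokine genes of the list, among them IL6 and CCL4, were listed at 0 or below 1 FPKM in U937.

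Targets of the lipid-sensing PPAR receptors had higher values as a group. Their median log2 ratio in U937 was 0.30, above that of every random list (percentile 100). PLIN2 (2.86) was the one member at 2-fold, the fatty acid transporter genes CD36 and SLC25A20 stood at 0.64 and 0.60, and UCP2 stood at -0.52. Of the 18 measured members, 14 lay above the median of all genes. Genes of the unfolded protein and integrated stress response had a median of 0.15 (percentile 98.2). DDIT4 (2.66), DDIT3 (1.66) and CHAC1 (1.61) were at least 2-fold higher, SESN2 stood at 0.98, and the other 27 members also differed by less than 2-fold. This percentile was 62.55 with the GC trend subtracted. Sterol synthesis genes lay at the low end, with a median of -0.07 (percentile 0.84) and no member at 2-fold. MVD stood at -0.60, SREBF2 at -0.39 and MVK at -0.35, while ACAT2 stood at 0.27. Of the 23 measured members, 8 lay above the median of all genes. With the GC trend subtracted MVD stood at -0.09, SREBF2 at -0.34, MVK at -0.19 and ACAT2 at 0.18, and the list still stood apart.

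Markers of blood cell types also differed between the U937 libraries. Markers of monocytes and macrophages had a median log2 ratio of 0.26 (percentile 99.2), with S100A8 at 1.55, CD68 at 0.53, FCGR1A at 0.46 and S100A9 at -0.51. S100A8 was low, at 1.08 and 5.06 FPKM in DMSO and EET, and FCGR1A shares its locus with another gene. Against log2 ratios taken without the added 1, the implied standard error was 1.09 for S100A8 (ratio 2.23) and 2.12 for FCGR1A (ratio 0.56). Markers of granulocytes and mast cells had a median of -0.32 (percentile 0.19). Neutrophil elastase, ELANE, stood at 139 FPKM in DMSO and 60.6 FPKM in EET, and azurocidin, AZU1, at 38.5 and 17.8 FPKM. Both genes are GC-rich, and with the GC trend subtracted their log2 ratios were -0.67 and -0.56 and the list lay at percentile 47.4. The haematopoietic transcription factors had a median of -0.03 (percentile 13.25), with 1 of 22 measured members at least 2-fold higher and 1 lower. HOXA9, in a locus of 5 genes, stood at 1.348 and CEBPB at 0.69 (1.30 and 1.20 with the GC trend subtracted). LYL1 stood at -1.23 and TCF3 at -0.68 (-0.71 and -0.39 with the GC trend subtracted), and RUNX1 at 0.15 (4.72 and 5.35 FPKM). The homing receptor gene CXCR4 stood at 81.0 and 96.6 FPKM in DMSO and EET. CD34 was listed at 0 in DMSO and at 0.065 FPKM in EET, and EPHX2, the gene of the soluble epoxide hydrolase that degrades EETs, was listed at 0 in both.

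Oxidative phosphorylation genes had a median of 0.06 at percentile 1.15, with NDUFB7 at -1.11 (-0.59 with the GC trend subtracted) and ATP5D at -1.82, and replication-dependent histone genes a median of 0.00 at percentile 0.01. With the GC trend described below subtracted these lists lay at percentiles 14.9 and 2.87 and no longer stood apart. Ribosomal protein genes had a median of 0.22 at percentile 64.2, and heat shock genes one of 0.18 at percentile 93.1, with HSPA6 at 1.25. In total 7 of 27 lists with at least 5 measured members stood apart, where fewer than 2 were expected by chance, and 4 of the 7 no longer did with the GC trend subtracted. In simulated data without differences, 2 of these lists stood apart. That simulation shuffled ratios among genes of like expression and so held no GC trend. Neither it nor the number expected by chance covers lists moved by GC content. The most abundant bins hold many snoRNA genes, so the percentiles of very abundant lists depend on them, and ribosomal protein genes lay at percentile 99.9 with small RNA genes left out.

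**Figure D2:**
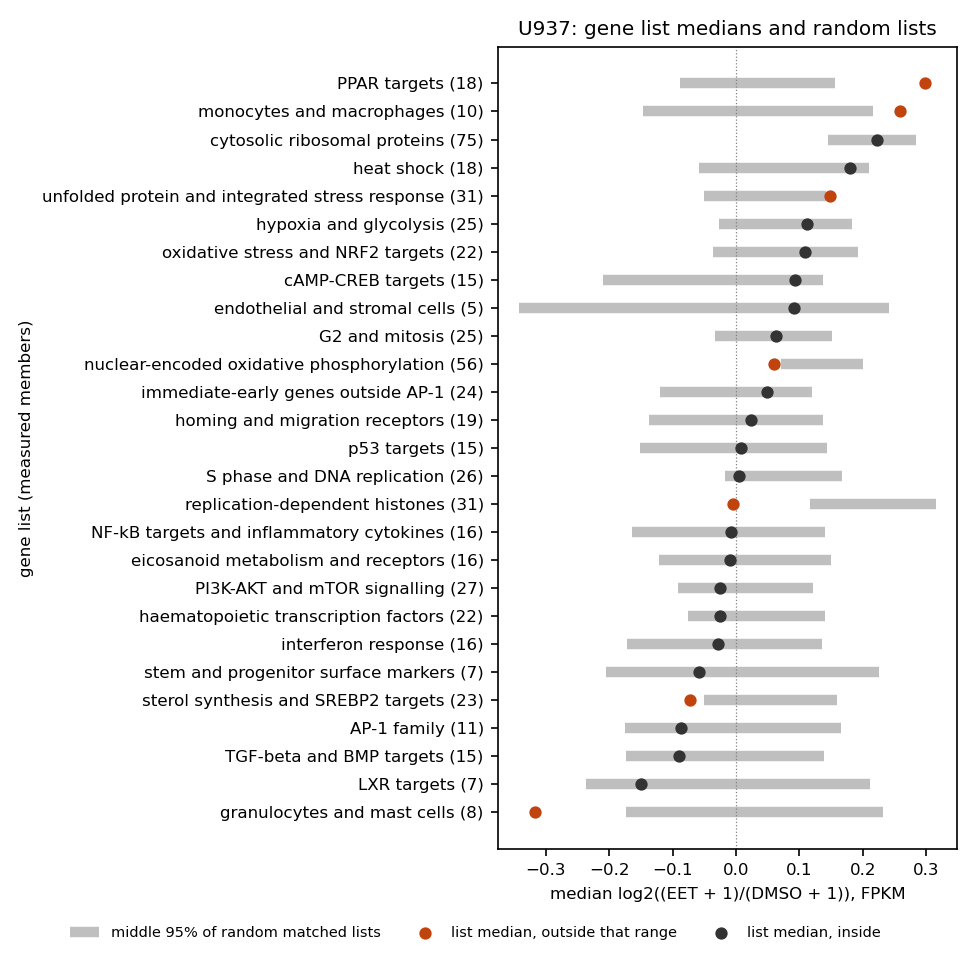
Median log2((EET + 1)/(DMSO + 1)) of each gene list in U937 (points) and the middle 95% of random lists matched on expression (grey bars), with the number of measured members in brackets. PPAR targets, at 0.30, lie to the right of their bar, and granulocyte and mast cell markers, at -0.32, to the left.

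The log2 ratios in U937 depended on the GC content of the gene. The median was -0.35 for the tenth of genes with the highest transcript GC content and 0.11 for the sixth decile, and Spearman's rho over all longer genes was -0.26. This correlation is across genes, which are not independent replicates. The longer genes at least 2-fold lower with EET had a median GC content of 64.4%, against 49.2% over all measured longer genes, and 26 of the 86 (30.2%) lay on chromosome 19, which holds 6.81% of the longer genes. MIF (66.7% GC), MBD3 (66.8%), SIVA1 (63.7%), LYL1 (69.2%) and ELANE (66.9%) belong to this group. With the median ratio of each GC bin subtracted, an alternative added after the data were examined, MIF stood at -1.21, SIVA1 at -1.07, MBD3 at -0.93 and LYL1 at -0.71. PLIN2, DDIT4 and FOS stood at 2.80, 3.18 and 2.01 under that subtraction, and the counts were 111 higher and 74 lower.

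**Figure D3:**
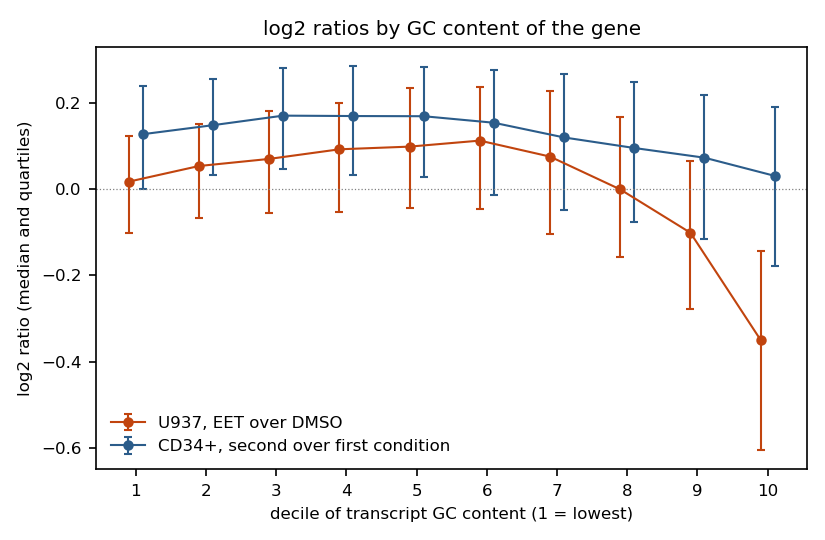
Median and quartiles of the log2 ratio of longer genes by decile of transcript GC content, for U937 (EET over DMSO, orange) and for the CD34+ table (second-listed over first-listed condition, blue). The U937 median is 0.11 in the sixth decile and -0.35 in the highest.

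For the CD34+ cells, the comparison asks which transcripts differ between EET and DMSO, but the files do not say which condition is which. By the authors' deposited table, 33 genes were marked significant, 21 with higher and 12 with lower values in the second-listed condition. The higher genes were led by cytokine and chemokine genes. According to the authors' deposited table, IL1A had a log2 ratio of 2.30 (4.93-fold), CCL20 one of 2.26, IL6 one of 2.00, CCL3 one of 1.72, IL1B one of 1.64 and CCL4 one of 1.54. IL1RN, the antagonist of the interleukin 1 receptor, stood at 1.68 in the authors' deposited table, TNFAIP6 at 1.63, IL8 at 1.07 and CXCL2 at 0.91. RMRP, the RNA of a ribonuclease complex, had the highest ratio of the authors' deposited table among these genes (2.55). Also higher in the authors' deposited table were G0S2, a lipase inhibitor (1.43), SERPINB2 (1.40), DUSP4 (1.20), the urokinase receptor gene PLAUR (1.07), HAS1 (0.93), AQP9 (0.91), the cyclooxygenase gene PTGS2 (0.88), SLC2A3 (0.78), CD69 (0.78) and PLIN2 (0.76).

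Of the 12 genes that the authors' deposited table marks as lower in the second-listed condition, SEMA3B had the lowest ratio, -1.75, followed by SLC9A3 at -1.41, YTHDC1 on a chromosome 4 contig at -1.39 and GOLGA8A at -1.33. Long non-coding RNA genes, MEG3 at -1.11 and NEAT1 at -0.83, were among them in the authors' deposited table. LOC728989, LOC100131564, TPM2, RNPC3, SEC31B and LENG8 had ratios of -1.15, -1.14, -1.12, -1.08, -0.91 and -0.88 in the authors' deposited table. The q-values in the authors' deposited table ran from 0 for IL1A, below the smallest value it prints, to 0.039 for PLIN2. With 1 library per condition these q-values rest on the spread that the authors' program assumed, not on replicates. As in U937, fewer tested genes had a p-value under 0.05 in the authors' deposited table than expected by chance.

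**Figure D4:**
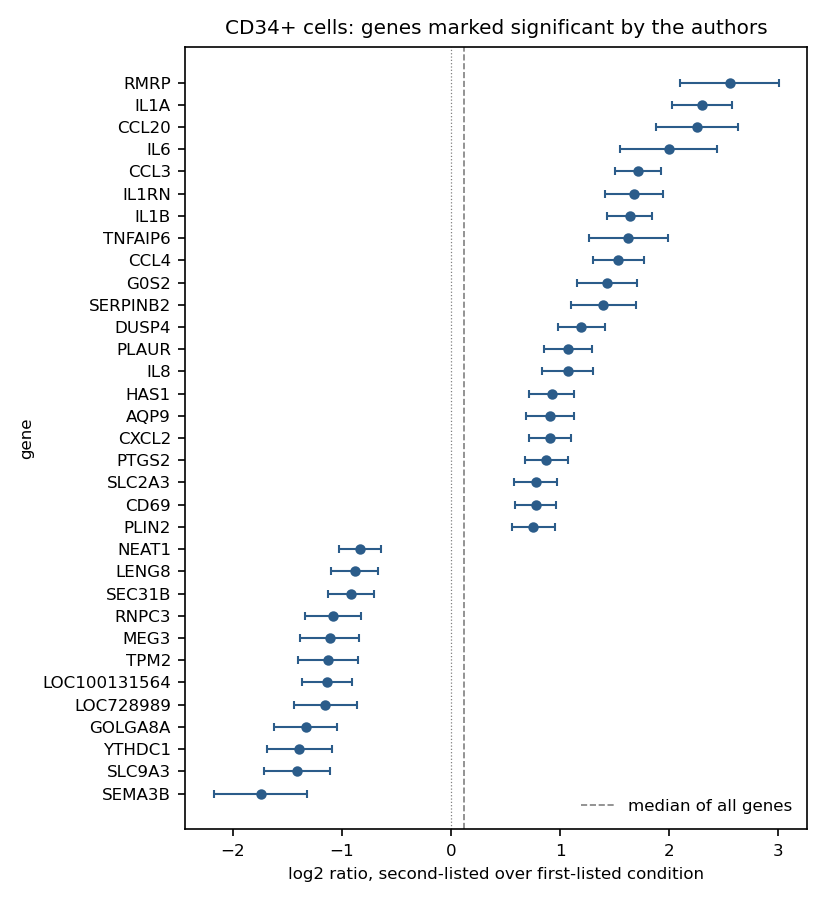
log2 ratio, second-listed over first-listed condition, of the 33 genes marked significant in the authors' deposited table for CD34+ cells, with bars of 1 standard error implied by its test statistic. RMRP (2.55) and IL1A (2.30) are at the top, SEMA3B (-1.75) is at the bottom, and the dashed line is the median of all genes, 0.12.

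Over the 14710 tested genes with a finite ratio in the authors' deposited table, the median log2 ratio was 0.12, so list medians are given relative to it. Ratios of single genes are given as deposited, without that median subtracted. By the authors' deposited table, 212 genes were at least 2-fold higher and 256 at least 2-fold lower in the second-listed condition, of which 27 and 60 were small RNA genes. With the ratios of the authors' deposited table centred on that median the counts were 163 higher and 338 lower, so the share of higher genes moved from 45.3% to 32.5%.

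NF-kB targets and inflammatory cytokines had the highest list median in the authors' deposited table, 0.47 above all genes. Of the 31 measured members in the authors' deposited table, 8 were at least 2-fold higher in the second-listed condition, none was 2-fold lower and 28 lay above the median of all genes. By the ratios of the authors' deposited table, AP-1 genes lay 0.31 above all genes, with no member of 13 at 2-fold. Beside a median of all genes of 0.12, FOSL2 stood at 0.70 in the authors' deposited table, FOSB and FOSL1 at 0.63, FOS at 0.60, JUNB at 0.59, JUND at 0.54, ATF3 at 0.40 and JUN at 0.15. Other immediate-early genes lay 0.29 above all genes in the authors' deposited table, DUSP4 being the only one of 37 at 2-fold, with NR4A3 at 0.86 and NR4A1 at 0.86. Targets of cAMP and CREB lay 0.34 above all genes in the authors' deposited table, with PDE4B at 0.69.

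These shifts were not limited to signalling genes. In the authors' deposited table all 75 ribosomal protein genes lay above the median of all genes, with a list median 0.26 above it, and oxidative phosphorylation genes lay 0.19 above it. Relative to all genes, heat shock genes lay 0.22 higher and markers of monocytes and macrophages 0.24 higher by the authors' deposited table, and both lists stood apart. Markers of erythroid cells, at -0.13 relative to all genes in the authors' deposited table (percentile 8.74), did not stand apart. Haematopoietic transcription factors lay 0.03 above all genes in the authors' deposited table. As deposited, beside a median of all genes of 0.12, RUNX1 stood at 0.29, LYL1 at 0.15 and MEIS1 at 0.31. CXCR4 stood at 0.63 in the authors' deposited table, CD34 at 0.36 and EPHX2 at -0.12, with an implied standard error of 0.47 for EPHX2. Of the 32 lists, 17 stood apart from random lists matched on the implied standard error of the authors' deposited table, all of them higher in the second-listed condition, against 1.6 expected by chance.

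The last comparison sets both cell types side by side, without a treatment direction for the CD34+ cells. Of the 33 genes marked in the authors' deposited table for CD34+ cells, 16 reached a mean of 1 FPKM in U937. Of the 8 measured in U937 that were higher in the second-listed CD34+ condition by the authors' deposited table, 6 had a U937 ratio above 0, and 2 (PLIN2 and IL8) were at least 2-fold higher with EET. SERPINB2 stood at 0.79 and SLC2A3 at 0.84 in U937, while RMRP stood at -0.76 and CD69 at -0.02. Of the 8 measured in U937 that were lower by the authors' deposited table, 6 had a U937 ratio below 0 and none was 2-fold lower, with NEAT1 at -0.72 and LENG8 at -0.67. YTHDC1 and LOC100131564, which were lower in the second-listed CD34+ condition, lay above 0 in U937, at 0.20 and 0.04. IL1A, IL1B and IL6, which are marked in the authors' deposited table for CD34+ cells, were listed at 0 or below 1 FPKM in both U937 libraries.

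Across the 10098 genes measured in both tables, the U937 ratios and those of the authors' deposited table for CD34+ cells had a Pearson correlation of 0.07 and a Spearman correlation of 0.12. Genes are not independent replicates, and the sign has no treatment meaning. At 2-fold, 8 genes were higher with EET in U937 and higher in the second-listed condition of the authors' deposited table, and 12 were higher in U937 and lower there, against 0.44 and 0.56 expected of independent lists. Of these, 6 and 11 were small RNA genes, and the others were IL8, BLOC1S5-TXNDC5 and HIST1H1T. Such expected numbers treat all genes alike, while small RNA genes made up 90 of the 132 genes higher in U937. The excess over them therefore does not measure a shared response. For genes lower with EET in U937, 0 were higher and 4 were lower in the second-listed condition of the authors' deposited table, with 0.40 and 0.52 expected, and HIST1H4L was the one gene among them that is not a small RNA gene.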

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

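The subtraction of GC bins, the removal of genes that share a locus or are listed at 0, and the other q-value thresholds were chosen after the results were seen. Part of the rule for named genes was also chosen after values were seen, and the matching of CD34+ random lists on the implied standard error after the files were, while the other settings were fixed before. With 1 library per group and no counts, depth sets limits that cannot be stated as intervals, and every count of genes at 2-fold rests on a size threshold alone. Pseudocounts, FPKM filters and a restriction to tested genes could not be run for the CD34+ table, where only ratios of tested genes were used. No named gene at 2-fold reversed under the settings run, but these settings could hardly have reversed one. Pseudocounts, filters and the removal of genes cannot change the sign of a ratio. Centring subtracted only the median of all genes, 0.029 in U937 and 0.12 in CD34+ cells. Subtracting GC bins moved the GC-rich gene TMEM238 from -1.99 to -1.47 in U937. Of the U937 values of named genes, 83 of 1426 moved beyond the standard error implied by the authors' statistic, or had none. No paired analysis was possible because the CD34+ conditions are not named and each cell type has 1 library per treatment. The causes below were not tested unless the setting itself removes genes.

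Of the 132 U937 genes higher and 130 lower with EET, 42 and 86 were left without small RNA genes, 40 and 72 without genes that share a locus, and 292 and 484 were counted at 1.5-fold. Lower genes numbered 238 with a pseudocount of 0.1, 64 with a pseudocount of 5 and 74 with GC bins subtracted. Of the CD34+ genes, 658 were higher and 657 lower at 1.5-fold, and 151 were lower without genes that share a locus. The authors' 33 marked CD34+ genes numbered 21 at a q-value of 0.01, and 11 U937 genes passed 0.1 in the authors' deposited table where none passed 0.05.

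The 8 genes higher in both tables numbered 2 without small RNA genes, 2 without shared loci and 5 with GC bins subtracted. The 12 genes higher in U937 and lower in the CD34+ table numbered 1 without small RNA genes and 2 without shared loci. The 0 genes lower in U937 and higher in the CD34+ table became 3 with a pseudocount of 0.1, 2 with no filter and 1 with GC bins subtracted. The 4 genes lower in both numbered 1 without small RNA genes, 1 without shared loci and 1 without genes listed at 0. The Pearson correlation of 0.07 was 0.049 at a mean of 5 FPKM, 0.13 without small RNA genes and 0.035 with GC bins subtracted, where the Spearman correlation was 0.052.

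With GC bins subtracted, the U937 lists of the stress response (percentile 62.55), oxidative phosphorylation (14.9), histones (2.87) and granulocytes and mast cells (47.4) no longer stood apart, while eicosanoid genes (99.6) and S phase genes (1.29) did. AP-1 genes of U937 went from 14.35 to 96.2, with a median of 0.15 in place of -0.09. In the CD34+ table the same subtraction put haematopoietic transcription factors at 99.4 and homing receptors at 97.1. The CD34+ stress response list lay at 97.3 centred on the median and 97.4 without small RNA genes. The U937 stress response list lay at 97.4 at a mean of 5 FPKM and oxidative phosphorylation at 2.81 without small RNA genes. Immediate-early genes and cAMP targets of U937 lay at 99.3 and 98.0 with no filter, heat shock genes at 97.7 and 98.0 with pseudocounts of 0.1 and 5, ribosomal protein genes at 99.9 without small RNA genes, and haematopoietic transcription factors of U937 at 1.25 at a mean of 5 FPKM. PPAR targets, sterol synthesis and monocyte markers stood apart in U937 under every setting run. For CD34+ cells, every list that stood apart did so under every setting run, except the stress response and homing receptors. NF-kB targets, AP-1 genes and other immediate-early genes were among the lists that held. So were ribosomal protein, oxidative phosphorylation, histone and heat shock genes and monocyte markers.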

Other observations

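The tests of GC content, of snoRNA length and host genes and of both explanations for the cytokine genes were chosen only after results were seen, and the tests of transcript length and chromosome 19 before.

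Small nucleolar RNAs, which guide chemical changes of ribosomal RNA, had higher values with EET in U937. Of 198 measured snoRNA genes 154 had a log2 ratio above 0 and 74 were at least 2-fold higher, with a median of 0.71, though 30 of 105 SNORD and 6 of 93 SNORA genes were listed at 0 in 1 library. The most abundant were SNORA63, at 47738.7 FPKM in DMSO and 74197.4 FPKM in EET, and SNORD10, at 37880.2 and 65422.7 FPKM. Small RNA genes together made up 38.4% of summed FPKM in DMSO and 49.5% in EET, while the abundant RNAs RMRP (10.7% and 5.37%) and RPPH1 (4.50% and 2.61%) had lower shares in EET. In the authors' deposited table for CD34+ cells, 66 of 166 snoRNA genes had a ratio above 0, with a median of -0.14. The 29 microRNA genes measured in U937 had a median of -3.66, and 18 of them were listed at 0 in 1 library.

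Of the heat shock and the hypoxia list in U937, 1 of 18 and 1 of 25 measured members were at least 2-fold higher, HSPA6 (0.39 and 2.29 FPKM in DMSO and EET) and DDIT4, and neither list stood apart (percentiles 93.1 and 69.6). HSPA1B, on a chromosome 6 contig, stood at 10.25 and 20.04 FPKM and VEGFA at 11.4 and 17.03 FPKM, both under 2-fold. The interferon-stimulated gene ISG15 stood at 23.7 and 10.3 FPKM in U937, a log2 ratio of -1.12 that was -0.61 with GC bins subtracted, its list lay at percentile 38.1, and the growth factor gene TGFB1 stood at 14.8 and 7.14 FPKM. According to the authors' deposited table for CD34+ cells, the platelet genes PF4 and PPBP had log2 ratios of 1.26 and 1.10 and GP6 one of -1.40, none of them marked significant. Their list held 3 members at least 2-fold higher and 1 lower and did not stand apart (percentile 89.49). The haem oxygenase gene HMOX1 stood at -0.70 in the authors' deposited table, also not marked. FTH1, MT2A and PRDX1 of the same oxidative stress list stood at 0.64, 0.49 and 0.45, and that list did not stand apart either (percentile 85.35).

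The longer genes lower with EET in U937 were GC-rich. Transcript length is argued against as the whole cause, since 98.8% of the 80 genes with a value (95% exact interval 93.2 to 99.97) stayed at least 2-fold lower with length bins subtracted. A shift of chromosome 19 as a whole is argued against as the main cause. Its 687 genes differed by a median of -0.027 (bootstrap interval -0.047 to -0.0081) from genes elsewhere of like GC content and expression. This difference is below 0 but small beside the 2-fold threshold. A median over all 687 genes cannot tell whether location plays a part for the 26 lower genes on that chromosome. A GC-dependent difference between both libraries may explain part of it, with 40% of the genes (29.2 to 51.6) still 2-fold lower once GC bins were subtracted and a median ratio of -0.87 in place of -1.17. Of the 80 genes, 32 stayed 2-fold lower, so most did not. The interval takes these genes as independent draws, which they are not. Treatment and library coincide, so a technical trend and an effect of EET on GC-rich transcripts cannot be told apart.

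In the CD34+ table the cytokine genes at 2-fold had a median ratio 1.55 above all genes, and the monocyte list also stood apart (0.24 above all genes, percentile 99.98, with 13 of 17 members above their median). More monocytes in the second-listed library was examined through 11 monocyte markers whose implied standard error was at least the median of these genes. They lay only 0.23 above all genes (bootstrap interval -0.31 to 0.28), from -3.49 for C1QB to 0.56 for CLEC7A. The implied error stands in for abundance, which was not measured, and 0 of 17 markers were 2-fold higher. These values argue against a general 2-fold rise of the markers. The cytokine genes were picked for their high ratios and the markers were not, and the whole NF-kB list lay 0.47 above all genes. The comparison therefore cannot decide whether more monocytes account for the cytokine genes. For a shift shared by abundant transcripts, the NF-kB list lay 0.23 above ribosomal protein and oxidative phosphorylation genes, with a bootstrap interval over genes of 0.0026 to 0.40, close to 0. That list includes the 8 genes at 2-fold that form the pattern, so its difference was partly built in and cannot decide against such a shift. AP-1 genes lay only 0.07 (-0.23 to 0.24) and other immediate-early genes 0.04 (-0.11 to 0.10) above the ribosomal protein and oxidative phosphorylation genes. An effect of the treatment on cytokine genes may remain as a hypothesis whose direction the files do not give, and differences in handling between the libraries were not tested.

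For the higher snoRNA values in U937, higher values of the genes that hold them are argued against as the whole cause. The most abundant longer gene in the locus of each of 170 snoRNA genes lay at a median of 0.13 above all genes (bootstrap interval over 104 loci 0.048 to 0.18), against 0.71 (0.59 to 0.87) for these snoRNA genes, and EIF4A2, which shares its locus with SNORA63, stood at 108 and 119 FPKM; an earlier version with SNHG genes and GAS5 alone gave 0.072 (-0.13 to 0.28). A difference that acts on transcripts shorter than the sequenced fragments could account for part of it, since the ratio was lower for longer transcripts across 186 snoRNA genes (Spearman's rho -0.24, bootstrap interval -0.37 to -0.09) and within SNORD genes (-0.29, -0.46 to -0.11). Within SNORA genes no trend was seen (0.08, -0.13 to 0.30), but this interval spans 0 and cannot decide. The microRNA genes, of a median length of 89.5 bases against 85 for SNORD genes, went the other way. Their median ratio was -3.66 (-6.59 to -0.21), although the 11 with values in both libraries had one of -0.07. With most microRNA genes at 0 in 1 library, shortness and an effect of EET on snoRNAs cannot be told apart.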
